A study of Sus scrofa with 12 samples.

How the data were processed

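RNA from whole blood of pigs was measured on single-colour Agilent arrays. There were 12 arrays in 6 groups of 2, from 2 housing rooms at 3 sampling times. One room was warmed by a gasoline heater and the other by a mineral heat ware, and the sample labels call the latter RAVI. Per the labels, 20 weaned pigs aged 6 weeks entered the rooms, were housed for 8 weeks and were vaccinated against atrophic rhinitis 2 weeks after entry. The design text counts the 2, 4 and 8 weeks from vaccination, whereas the sample descriptions give them as weeks of rearing, so the times are used here only as labels. Counted from vaccination, the 8-week label would fall after the stated 8 weeks of housing. No array is labelled as taken before vaccination, and on the rearing count the 2-week arrays fall at it. The labels do not say whether an array holds 1 pig or a pool. Each p-value therefore measures only the spread between these arrays, which may be partly technical, and heater and room cannot be separated because each heater had its own room.

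The intensity values in the files as deposited are processed signals, made per the file headers by Agilent Feature Extraction 11.0.1.1. They are the software's final spot signals after background subtraction and its further corrections, whose settings the headers do not list, and they are positive for each spot, also where the background-subtracted column is negative. They were not scaled between arrays, since their 75th percentiles ranged from 129.7 to 311.3. Each array held 43803 gene spots for 43603 probes, and 50 probes were spotted 5 times each and averaged. Symbols came from the RefSeq accessions that the files give for 7111 probes. Of these, 425 matched no gene in the table used, which left 6686 probes (15.3%) with 1 symbol, for 3020 genes. The remaining 36917 probes carry transcript, expressed-sequence or manufacturer identifiers and are reported as unnamed. No probe had several symbols.

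The log2 of the processed signal was lowered by each array's 75th percentile. A probe was tested where the scanner software called it well above background on both arrays of at least 1 group, which 22288 probes met. For each gene with a symbol the brightest tested probe was used, which gave 17094 features, 2092 named and 15002 unnamed. Depth on an array is signal over background: 42.2% to 53.3% of probes were well above background and 0 spots were saturated. The number of arrays limits the precision.

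A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and 6 residual degrees of freedom. RAVI minus gasoline heater was tested averaged over the 3 times and at each time. The 3 times were compared in pairs, averaged over heaters, and by F tests within each heater and for the interaction of heater with time. Benjamini-Hochberg adjusted p under 0.05 within each comparison was the threshold. A fold against a group whose arrays were all below background is given as a bound where each array on the other side was above it, computed from the lowest signal called well above background, and no fold is given where both groups were below it. Where only some arrays of a group were below background, the log2 difference is given as measured and its size is not exact.

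In all, 36 gene lists for blood cell types, immune responses, stress and metabolism were fixed, of which 31 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, against all named features. With an estimated correlation camera called 0 lists in each comparison, and fry called between 8 and 29. Unadjusted p was under 0.05 with the estimated correlation for 2 lists in the averaged heater comparison, 4 at 2 weeks, 1 at 4 weeks and 3 at 8 weeks. For 4 minus 2, 8 minus 4 and 8 minus 2 weeks these numbers were 2, 0 and 1. Of the 8 genes in the granule-protein list, 0 stand in another fixed list; 9 of the 22 in the monocyte list and 5 of the 11 in the glucocorticoid list do. The fixed lists, tests, alternatives and the rule for named genes were written before the data were examined.

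The rule names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap. For the averaged heater effect it asks for the same sign at all 3 times instead. It adds up to 4 members of each called list with the smallest p in the list's direction, 5 genes per F test, and a preset group of immune and stress genes in the heater comparisons. A few genes that the rule names are not reported here. Of that group, IL6, IL4 and CYP1A1 were on the array but too dim to test. XIST, DDX3Y, the hemoglobin genes and HSPA1A matched no symbol. The dendritic, plasma cell, gamma delta T, xenobiotic and sex-linked lists had fewer than 5 measured genes and were not tested.

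Each slide carried 4 arrays, and the 2 heater arrays that share a time and a replicate number always shared a slide, at neighbouring positions. RAVI arrays stood at even positions throughout. The replicate numbers pair the arrays through the slide: after removal of group means, same-numbered arrays of the heaters correlated across features by 0.391 at 2 weeks, 0.418 at 4 weeks and 0.229 at 8 weeks. A fit with slide as a fixed block, and one with the 6 slide pairs as the block, were therefore run beside each result. Values with slide as a block are printed where a call was lost or a count moved by over 1.5 times. With the slide pairs as the block only such counts and lost list calls are printed, and no values of single genes. Of the features called at 2, 4 and 8 weeks, 172 of 267, 87 of 231 and 774 of 873 were also called with the pair block. A single-gene call at 1 time or for the interaction may therefore be lost under it.

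The fit was tested on simulated data of 17094 features, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. For the averaged heater effect it recovered 46.3% of features changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 97.0% of those changed by 2, with 8 false calls among 158. At 2 weeks alone these shares were 3.0%, 58.2% and 93.9%, with 5 false calls among 108. For 8 minus 2 weeks they were 34.3%, 79.1% and 92.4%, with 6 false calls among 143. For the interaction, a size of 0.5 was recovered in 0%, a size of 1 in 22.4% and a size of 2 in 81.8%. A list shifted by 0.5 was called, and 0 of the other lists were. The simulated noise was drawn independently for each feature and array, without slide effects or correlation within lists. In the real data the estimated correlation in the ribosomal list was 0.79. The simulation therefore cannot show how list calls fare under such correlation. The adjusted threshold also depends on the share of changed features. In the real data 11090 features were called for 8 minus 2 weeks, far more than were changed here, so the recovered shares need not hold there.

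Other scalings, filters, probe summaries, models, blocks and list tests were tried, each array was left out in turn, and the closing section gives their effect. Normexp correction on mean spot signals was replaced by median spot signals, because the tables used here hold no mean. Data on vaccine response or growth were not analysed here.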

Results

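The study asked how rearing pigs with mineral heat ware (RAVI) rather than a gasoline heater changes gene expression in whole blood around a vaccination, per its title and design text. Each of 2 heaters was sampled at labels of 2, 4 and 8 weeks, with 2 arrays per group and 12 in all. Replicate arrays of a group correlated across features at r = 0.984 to 0.993. Arrays of the same time and different heaters correlated at 0.980 to 0.990, and arrays of different times at 0.935 to 0.982. These correlations are across features, which are not independent replicates. The first principal component held 51.4% of the variance, and time accounted for 99.1% of it. The third held 6.5%, with 55.0% of it by heater, and the fourth held 5.9%, with 72.3% of it by slide. Values below are differences in log2 signal with their standard error (SE), each group mean resting on 2 arrays.

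The averaged heater comparison asks which genes differed between the rooms on average over the 3 times. Genes for the antimicrobial peptides and proteins that neutrophil precursors store in granules were higher with RAVI. PMAP-23 (gene ID 100170138) was higher by 2.20 (SE 0.092, 4.58-fold, adjusted p = 3.13e-05), PR39 (407610) by 1.75 (SE 0.060, 3.37-fold, adjusted p = 1.78e-05) and NPG4 (396871) by 1.69 (SE 0.067, 3.22-fold, adjusted p = 2.67e-05), each in 6 of 6 slide pairs. All 3 encode cathelicidins, host defence peptides of pig neutrophils. The iron-binding granule protein LTF (397649) was higher by 1.01 (SE 0.066, 2.01-fold), and PMAP-36 by 1.46 (SE 0.212) in 5 of 6 pairs, although above background on only 2 of 6 gasoline heater arrays and 5 of 6 RAVI arrays. Of the 8 measured genes of the fixed granule-protein list, 7 were higher, also 7 adjusted over the list alone, with a list median of +1.24 (camera adjusted p = 3.35e-07, adjusted p = 0.149 with an estimated correlation).

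Genes of cytotoxic lymphocytes were also higher with RAVI. KLRK1 (396737), which encodes the activating receptor NKG2D, was higher by 0.94 (SE 0.070, 1.92-fold, adjusted p = 0.000555). The death ligand FASLG was higher by 0.65, the chemokine XCL1 by 0.64 and the granule protein NKG7 by 0.61, each in 6 of 6 pairs. Of the 13 measured genes of this list 8 were higher and 0 lower (9 adjusted over the list alone), with a median of +0.53 (camera adjusted p = 3.5e-05, adjusted p = 0.687 with an estimated correlation). Among myeloid genes, the calgranulins S100A8 (+0.83, SE 0.073), S100A12 (+0.73, SE 0.063) and S100A9 (+0.73, SE 0.059) were higher, as was the receptor TREM1 (+0.42). In the neutrophil list 5 of 11 genes were higher and 1 lower, 7 and 2 adjusted over the list alone, with a median of +0.26. In the monocyte list 6 of 22 were higher and 0 lower (9 and 1 adjusted over the list alone), with a median of +0.16. These were led by the haemoglobin scavenger receptor CD163 (+1.06, SE 0.097), the endotoxin co-receptor CD14 (+0.73, SE 0.084), haem oxygenase HMOX1 (+0.70, SE 0.070) and FCN1 (+0.42). The neutrophil call (adjusted p = 0.0364) and the monocyte call (adjusted p = 0.0393) were lost with slide as a block, at adjusted p = 0.0537 and 0.0639. Both stood at adjusted p = 0.687 with an estimated correlation.

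Red cell precursor genes were lower with RAVI. RHCE, a blood group protein, fell by 0.58 (SE 0.056) in 6 of 6 pairs. The transferrin receptor TFRC also passed (-0.65, SE 0.141), although it was below background in both groups at 2 and 4 weeks. KLF1 had -0.32 (adjusted p = 0.0998). Of the 6 measured genes of this list 3 were lower and 0 higher (4 lower adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.00207, adjusted p = 0.149 with an estimated correlation). The water channel AQP1, found on red cells, fell by 0.87 (SE 0.096). In the platelet list 2 of 14 genes were lower (3 adjusted over the list alone), THBS1 (-0.32, SE 0.056) and ITGA2B (-0.22, SE 0.051), while TUBB1 (-0.22) and MYL9 (-0.29) did not pass. Its median was -0.13 (camera adjusted p = 0.0166, adjusted p = 0.687 with an estimated correlation), and +0.13 with the 8-week arrays left out. The ribosomal protein list had a median of -0.13, and 0 of its 34 genes passed (also 0 adjusted over the list alone). Its call (adjusted p = 3.77e-06, adjusted p = 0.687 with an estimated correlation) was lost under quantile scaling, where the median was +0.01 (adjusted p = 0.347), and under normexp, with +0.02 (adjusted p = 0.37). RPS21 (-0.25), RPL6 (-0.24), RPL11 (-0.23) and RPL23 (-0.21) had the smallest p in it.

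Smaller shifts met the list test for 3 further groups. In the helper T cell cytokine list 3 of 10 genes were higher, 4 adjusted over the list alone: IFNG (+0.46, SE 0.066), IL4R (+0.36, SE 0.062) and IL10 (+0.35, SE 0.065, 4 of 6 pairs), beside IL12RB1 with +0.22 (adjusted p = 0.0549). In the heat shock list 0 of 11 passed over all features and 7 were higher adjusted over the list alone, HSPH1 with +0.31, HSPB1 with +0.30, HSPD1 with +0.26 and HSPA8 with +0.25. In the glucocorticoid list 4 of 11 were higher (5 adjusted over the list alone): CD163, the transcription factor CEBPB (+0.71, SE 0.095, above background on 2 of 6 gasoline heater and 4 of 6 RAVI arrays), ALOX5AP (+0.39) and DDIT4 (+0.27, 4 of 6 pairs). The list medians were +0.17, +0.25 and +0.15, at camera adjusted p = 0.0241, 0.0393 and 0.0393. All 3 stood at adjusted p = 0.687 with an estimated correlation, and the glucocorticoid list at 0.0639 with slide as a block. CD8A was higher by 0.32 (adjusted p = 0.0151), whereas TNF (+0.10), IL1B (-0.01, and +0.03 under median scaling) and CD4 (-0.17) did not pass.

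Other named genes higher with RAVI were the elastase CELA2A (+1.26, SE 0.095) and PTH1R, the parathyroid hormone receptor (+0.84, SE 0.070), and NPM2 (-0.70) was lower. Further genes passed but were below background on part of the arrays, so their sizes are not exact and are not ranked. Of the 6 gasoline heater and 6 RAVI arrays, FXYD2 (+1.51) was above background on 1 and 4, the epithelial adhesion gene EPCAM (-1.69) on 3 and 1, PAGE2B (-0.87) on 6 and 4, HPSE (-0.83) on 2 and 3, LOC100626841 (-0.78) on 3 and 1, TRIM10 (-0.73) on 4 and 3, and LPL, a lipase (-1.03), on 2 and 0. SRPK3 (-1.38) was above background on only 2 of 6 gasoline heater arrays and 0 RAVI arrays, so no fold is given. In total 1221 of 17094 features differed, 740 higher and 481 lower with RAVI, against 3978 at unadjusted p under 0.05. Without the filter on dim probes the number was 236, and without gasoline heater replicate 1 at 8 weeks it was 511. It was 116 without the 8-week arrays and 468 without the 2-week arrays. Of the 234 named ones, 175 were higher. Of the 1221, 983 had the same sign at all 3 times and 829 in all 6 slide pairs, which choosing them by the averaged effect favours. Among all tested features 17.4% had 1 sign in all 6 pairs. With slide as a block the number was 2816, and with the 6 slide pairs as the block 2099. The higher share of the calls, 60.6%, was 71.0% under median scaling (446 higher, 182 lower) and 51.1% where the 75th percentile was taken over probes above background on all arrays (704 and 675).

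**Figure D1:**
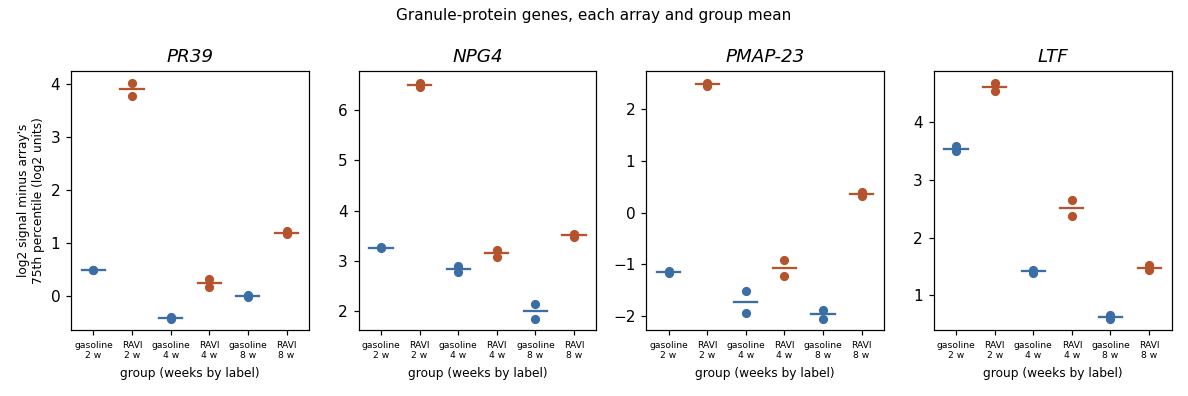
Signals of 4 granule-protein genes (log2 units relative to each array's 75th percentile, vertical axis) in the 6 groups (horizontal axis); points are arrays and lines are means of 2 arrays. RAVI means lie above gasoline heater means at each time, for PR39 by 3.41 at 2 weeks, 0.66 at 4 weeks and 1.19 at 8 weeks.

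At 2 weeks the cathelicidin genes PMAP-23, PR39 and NPG4 showed their largest differences. PMAP-23 was higher with RAVI by 3.62 (SE 0.160, 12.3-fold), PR39 by 3.41 (SE 0.104, 10.6-fold), NPG4 by 3.25 (SE 0.116, 9.49-fold) and PMAP-36 by 2.71 (SE 0.367, with 1 of 2 gasoline heater arrays above background). LTF (+1.07, SE 0.115) and LCN2, the siderophore-binding granule protein (+1.24, SE 0.133), were higher by less. The list had 7 of 8 genes higher, also 7 adjusted over the list alone, with a median of +1.98 (camera adjusted p = 5.24e-10, adjusted p = 0.12 with an estimated correlation). FABP6 (397423), an ileal bile acid binding protein, was at least 8.03-fold higher (+4.55, SE 0.110, adjusted p = 1.41e-06). It and the slow muscle genes TNNC1 (+3.92, at least 9.14-fold), TNNT1 (+3.74, at least 9.96-fold) and MYL2 (+3.46, at least 2.61-fold) were below background on both gasoline heater arrays and above it on both RAVI arrays. A further slow muscle gene, MYH7, had a mean signal of -3.88 with the gasoline heater and -0.01 with RAVI, whereas ACTA1 was 5.05 with the gasoline heater and 5.11 with RAVI. MYH7 and ACTA1 were looked up after the values above had been seen.

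Cell division genes were higher at 2 weeks, with the mitotic cyclin CCNB1 at +0.93 (SE 0.123) and the histone H2AFZ at +0.62 (SE 0.115), beside CCNB2 (+0.95, adjusted p = 0.0875) and CDK1 (+0.77, adjusted p = 0.0666). In that list 2 of 11 passed, 6 adjusted over the list alone, with a median of +0.56 (camera adjusted p = 0.0013, adjusted p = 0.354 with an estimated correlation). Interferon-induced antiviral genes were lower: IFIT1 fell by 0.65 (SE 0.102) and ZBP1 fell by 0.53 (SE 0.098, 1 of its 2 probes in this direction), while RSAD2 had -0.50 (adjusted p = 0.0549) and MX2 had -0.40. Of the 22 genes 2 were lower and 0 higher (11 lower and 2 higher adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.59e-07, adjusted p = 0.306 with an estimated correlation). In the cytotoxic list KLRK1 (+0.78) and XCL1 (+0.61) passed among 13 genes (5 adjusted over the list alone), while FASLG (+0.46) and NKG7 (+0.61) did not, and the median was +0.28 (camera adjusted p = 0.00477, adjusted p = 0.979 with an estimated correlation). In the erythroid list 2 of 6 were lower, RHCE (-0.77) among them (2 adjusted over the list alone), TFRC (-0.62, below background in both groups) and FAM210B (-0.10) did not pass, and the median was -0.37 (camera adjusted p = 0.00444, adjusted p = 0.191 with an estimated correlation). The heat shock list had a median of +0.33 with 0 of 11 past the threshold (6 adjusted over the list alone), HSP70.2 at +0.57, HSPH1 at +0.53, HSPB1 at +0.48 and HSPD1 at +0.41. The respiratory chain list had +0.27 with CYCS (+0.54) past it among 14 genes (also 1 adjusted over the list alone), beside SDHD (+0.36), NDUFV2 (+0.35) and UQCRB (+0.34). These 2 stood at camera adjusted p = 0.0256 and 0.0304, and both at adjusted p = 0.979 with an estimated correlation.

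Other named falls at 2 weeks were PAGE2B (-1.49), AQP1 (-0.92), CMYA5 (-0.85), the arginase ARG1 (-0.76), RSPH9 (-0.67), ASPN (-0.63) and FBXO9 (-0.60), and CELA2A was higher by 1.40. IFNG was higher by 0.71 (adjusted p = 0.0283), while HMOX1 (+0.47), CD8A (+0.37), CD4 (+0.31), IL10 (+0.21) and TNF (+0.12) did not pass, nor did IL1B (0 to the third decimal). In all 267 features differed, 176 higher and 91 lower, of which 69 were named, and far fewer were called in a fit to only the 2-week arrays (closing section). With slide as a block the number was 684. The higher share of 65.9% was 77.1% under median scaling (64 higher, 19 lower) and 59.9% with the percentile over probes above background on all arrays (191 and 128). Without RAVI replicate 1 at 2 weeks 30 features passed, and without the filter on dim probes 28.

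At 4 weeks interferon-induced genes were higher with RAVI rather than lower. MX1 (397128) was higher by 0.87 (SE 0.126), OAS2 by 0.83 (SE 0.133), RSAD2 by 0.61 (SE 0.098) and the kinase EIF2AK2 by 0.49 (SE 0.083). Of the 22 list genes 6 were higher and 0 lower (9 and 1 adjusted over the list alone), with a median of +0.29 (camera adjusted p = 2.37e-05, adjusted p = 0.49 with an estimated correlation). Myeloid and migration genes were also higher: CD14 by 1.02 (SE 0.146), CD163 by 0.95 (SE 0.168), TLR4 by 0.78 (SE 0.136) and the chemokine receptor CCR1 by 0.64, with S1PR5 (+0.63) and the integrin ITGB2 (+0.56). The adhesion list had 4 of 18 higher (6 and 1 lower adjusted over the list alone, median +0.24, camera adjusted p = 0.00184), the monocyte list 3 of 22 (7 and 1 lower adjusted over the list alone, median +0.18, camera adjusted p = 0.0038). These 2 lists stood at adjusted p = 0.49 and 0.499 with an estimated correlation. FASLG was higher by 0.99 (at least 1.68-fold), the only one of 13 cytotoxic genes to pass (5 adjusted over the list alone, median +0.15, camera adjusted p = 0.00169, adjusted p = 0.49 with an estimated correlation), beside CCL5 (+0.69), GZMB (+0.54) and XCL1 (+0.43). LTF (2.15-fold) and PR39 (+0.66, SE 0.104) were 2 of 8 granule-protein genes to pass (3 adjusted over the list alone, median +0.25, camera adjusted p = 0.0266, adjusted p = 0.49 with an estimated correlation), while PMAP-23 (+0.66), NPG4 (+0.31) and LCN2 (-0.32) did not.

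Antigen presentation and housekeeping lists were lower at 4 weeks without single genes past the threshold. The MHC class II list had a median of -0.32 (0 of 11, 7 adjusted over the list alone, camera adjusted p = 0.000182, adjusted p = 0.49 with an estimated correlation), with SLA-DOA at -0.56, SLA-DMB at -0.42, SLA-DQB1 at -0.36 and SLA-DQA1 at -0.32. The B cell list had -0.27 (0 of 7, 4 lower and 1 higher adjusted over the list alone, adjusted p = 0.499 with an estimated correlation), with CD79A at -0.54, BLNK at -0.45, CD72 at -0.34 and MS4A1 at -0.27. The ribosomal list had -0.31 (0 of 34, and 0 adjusted over the list alone, camera adjusted p = 1.85e-10, adjusted p = 0.49 with an estimated correlation), with RPS16 and RPL23 at -0.52, RPL10A at -0.45 and RPL22 at -0.44. The respiratory chain list had -0.28 (0 of 14, 6 adjusted over the list alone, camera adjusted p = 0.000182, adjusted p = 0.49 with an estimated correlation), with NDUFB8 at -0.51, COX6C at -0.43, ATP5O at -0.38 and CYCS at -0.34. The erythroid list had -0.55 with RHCE (-0.57) past the threshold among 6 (4 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation), TFRC at -0.79 (below background in both groups) and KLF1 at -0.55. The B cell call (camera adjusted p = 0.0367) and the erythroid call (0.0266) were lost with slide as a block, at adjusted p = 0.0896 and 0.086.

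Of 5 further lists higher at 4 weeks, the glucocorticoid list had CEBPB (+1.53, at least 1.90-fold) and CD163 past the threshold among 11 (4 adjusted over the list alone, median +0.09, camera adjusted p = 0.00578, adjusted p = 0.49 with an estimated correlation), beside ALOX5AP (+0.52) and TXNIP (+0.38). The complement list had ITGB2 among 9 (4 adjusted over the list alone, median +0.28, camera adjusted p = 0.0038, adjusted p = 0.49 with an estimated correlation), beside C5AR1 (+0.56, 1 of 2 probes), SERPING1 (+0.47) and C1QB (+0.96, below background in both groups). The neutrophil list had 0 of 11 (2 higher and 1 lower adjusted over the list alone, median +0.25, camera adjusted p = 0.0212, adjusted p = 0.499 with an estimated correlation), with S100A9 at +0.44, NCF1 at +0.35, S100A12 at +0.34 and TREM1 at +0.31. The inflammatory cytokine list had 0 of 17 (4 higher and 1 lower adjusted over the list alone, median +0.15, camera adjusted p = 0.0267, adjusted p = 0.499 with an estimated correlation), with CSF3 at +0.72, TNFSF13B at +0.54, TNFSF10 at +0.53 and IL18 at +0.30. The helper cytokine list had 0 of 10 (1 adjusted over the list alone, median +0.19, camera adjusted p = 0.0309, adjusted p = 0.499 with an estimated correlation), with IL4R at +0.49, GATA3 at +0.34, LAG3 at +0.29 and IFNG at +0.24.

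Other single genes higher at 4 weeks were FABP6 (+2.15, SE 0.110, with 1 of 2 gasoline heater arrays above background), CELA2A (+1.47) and GPAT4 (+1.02). BPIFA2, a salivary protein gene (+3.68, at least 2.58-fold), and FXYD2 (+2.53, at least 2.50-fold) were below background on both gasoline heater arrays, so only the bounds hold for them. MUL1 (+2.01) passed with 1 of 4 arrays above background. The falls were FAM213B (-0.98), SERPINF1 (-0.68) and SLC38A6 (-0.58), beside RHCE. HMOX1 (+0.63, adjusted p = 0.0523), CD8A (+0.24), TNF (+0.06), CD4 (-0.07), IL10 (-0.10) and IL1B (-0.46) did not pass. Altogether 231 features differed, 170 higher and 61 lower, 48 of them named. With slide as a block the number was 539 and with the 6 slide pairs as the block 95, of which 87 were among the 231. Without RAVI replicate 1 at 4 weeks it was 49, without the filter on dim probes 16, and limma on the 4 arrays of that time alone called 0, with 1003 at unadjusted p under 0.05.

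At 8 weeks cytotoxic genes were higher with RAVI and platelet genes were lower. KLRK1 was higher by 1.71 (SE 0.122, 3.26-fold, adjusted p = 0.000222), the granzymes GZMA by 1.66 (SE 0.164, 3.17-fold) and GZMB by 0.84 (SE 0.113), and XCL1 by 0.87 (SE 0.098). Of 13 cytotoxic genes 6 were higher and 0 lower (8 adjusted over the list alone), with a median of +0.49 (camera adjusted p = 4.51e-05, adjusted p = 0.599 with an estimated correlation). The platelet genes VWF (-1.46, SE 0.166), CLU (-1.21, SE 0.095), ITGA2B (-0.92, SE 0.088) and TUBB1 (-0.82, SE 0.107) were lower, with 6 of 14 lower and 0 higher (7 adjusted over the list alone) and a median of -0.76 (camera adjusted p = 1.54e-06, adjusted p = 0.252 with an estimated correlation). Granule-protein genes were again higher, PMAP-23 by 2.32 (SE 0.160, 4.98-fold), NPG4 by 1.51 (SE 0.116), PR39 by 1.19 (SE 0.104) and LCN2 by 1.05 (SE 0.133). In that list 5 of 8 passed (7 adjusted over the list alone), with a median of +1.12 (camera adjusted p = 2.58e-06, adjusted p = 0.252 with an estimated correlation). The calgranulins S100A9 (+1.13), S100A8 (+1.01) and S100A12 (+0.89) and TREM1 (+0.71) were among the 6 of 11 neutrophil genes that were higher, with 1 lower (7 and 1 adjusted over the list alone, median +0.56, camera adjusted p = 0.0076, adjusted p = 0.683 with an estimated correlation). The erythroid list had a median of -0.42 with 0 of 6 past the threshold (3 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.252 with an estimated correlation), TFRC at -0.53 and RHCE at -0.40.

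Some genes active in immature lymphocytes were lower with RAVI at 8 weeks. The recombinase genes RAG2 (100151744, -4.34, SE 0.352, at least 4.39-fold lower) and RAG1 (397506, -4.16, SE 0.931, at least 6.77-fold lower) and the lipid-presenting CD1E (-2.10, at least 1.68-fold lower) were above background on both gasoline heater arrays and below it on both RAVI arrays. The surrogate light chain VPREB1, in contrast, was higher by 0.59 (adjusted p = 0.0261). The other T cell markers were mixed, and all but PTCRA, CD4 and CD8A were looked up after this was seen. PTCRA, the pre-T-cell receptor chain, had -1.09 and -3.16 in the pairs, LEF1 -0.85 and -0.90, CD1.1 -0.60 and -0.55, CD4 -0.81 and -0.67, and AQP3 -0.40 and -0.23, against CD8A with 0.37 and 0.35, CD3E with 0.17 in both and LCK with 0.03 and 0.01. PTCRA was above background on 5 of 12 arrays. It also stands in the fixed platelet list, which was lower with RAVI at 8 weeks, so its fall cannot be assigned to T cells alone. FABP6, higher with RAVI at 2 and 4 weeks, was lower by 5.08 on the log2 scale at 8 weeks (-5.08, SE 0.110, 33.8-fold, adjusted p = 5.79e-07). EPCAM (-3.47, at least 7.94-fold lower), MUL1 (-3.18, at least 8.39-fold lower), SRPK3 (-2.42, at least 1.65-fold lower), LOC100302368 (-1.93, SE 0.167) and CNN1, a smooth muscle gene (-1.64, with 1 of 4 arrays above background), were also lower. C1QB (-1.82) passed but was below background in both groups.

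Further rises at 8 weeks were PTGFR, a prostaglandin receptor (+3.68, at least 2.65-fold), VWA7 (+1.59, at least 2.50-fold), the cytokine IL18 (+1.41, SE 0.098), the chemokine CCL3L1 (+1.31, SE 0.228), and MYBPH (+1.21). FXYD2 (+1.22) passed but was below background in both groups. IL10 (+0.95, adjusted p = 0.00326) and HMOX1 (+0.98, adjusted p = 0.00387) were higher and CD4 was lower (-0.74, adjusted p = 0.0479). IL1B (+0.44), IFNG (+0.42), CD8A (+0.36, 1 of 2 probes) and TNF (+0.13) did not pass. The 873 features called comprised 461 higher and 412 lower, 166 of them named, and fewer were called in a fit to only the 8-week arrays (closing section). With slide as a block there were 1677. The share of higher calls, 52.8%, was 39.7% where the 75th percentile was taken over probes above background on all arrays (408 higher, 619 lower) and 56.1% under median scaling (287 and 225). Leaving out RAVI replicate 2 at 8 weeks gave 218, and leaving out the filter on dim probes 199.

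**Figure D2:**
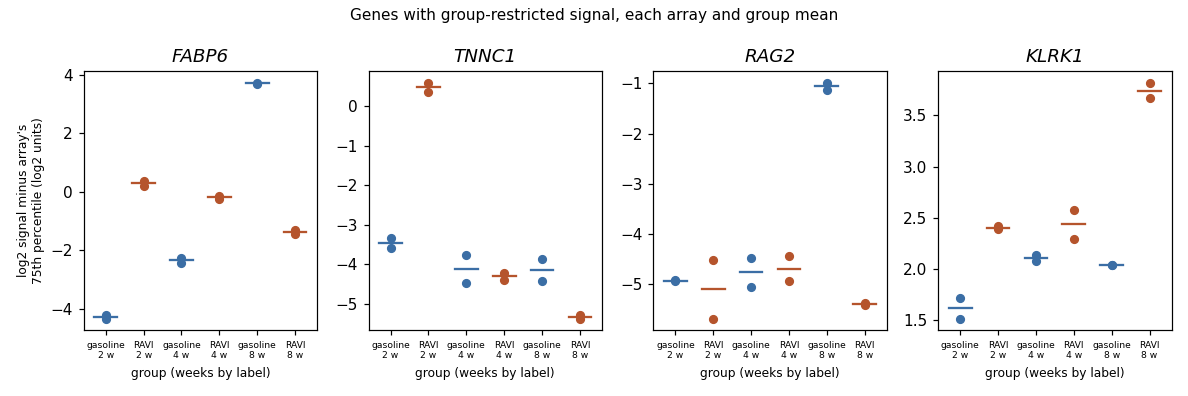
Signals of 4 genes (log2 units relative to each array's 75th percentile, vertical axis) in the 6 groups (horizontal axis); points are arrays and lines are means of 2 arrays. TNNC1 is high in RAVI at 2 weeks (mean 0.47), RAG2 in the gasoline heater group at 8 weeks (mean -1.06), and FABP6 runs from -4.27, below background, to 3.70 over the gasoline heater times.

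Features called at 2 times are set here against the numbers for independent calls. The calls are not independent, because both times use 1 variance estimate per feature and share slides, so a feature with a small variance passes more easily at both, in either direction. Of the calls at 2 and 4 weeks 35 were higher at both (1.75 if independent), 17 lower at both (0.325) and 5 opposite (1.53). At 2 and 8 weeks 50 were higher at both (4.75), 25 lower at both (2.19) and 32 opposite (6.70). At 4 and 8 weeks 62 were higher at both (4.58), 11 lower at both (1.47) and 16 opposite (5.74). The heater effect itself differed among times for 310 features by the interaction test, 64 of them named, led by FABP6 (adjusted p = 1.4e-07), MUL1 (6.03e-05), PR39 (0.000125), NPG4 (0.000212) and CLU (0.000403). With slide as a block this count was 566, with the 6 slide pairs as the block 171, without gasoline heater replicate 2 at 8 weeks 111 and without the filter on dim probes 79.

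**Figure D3:**
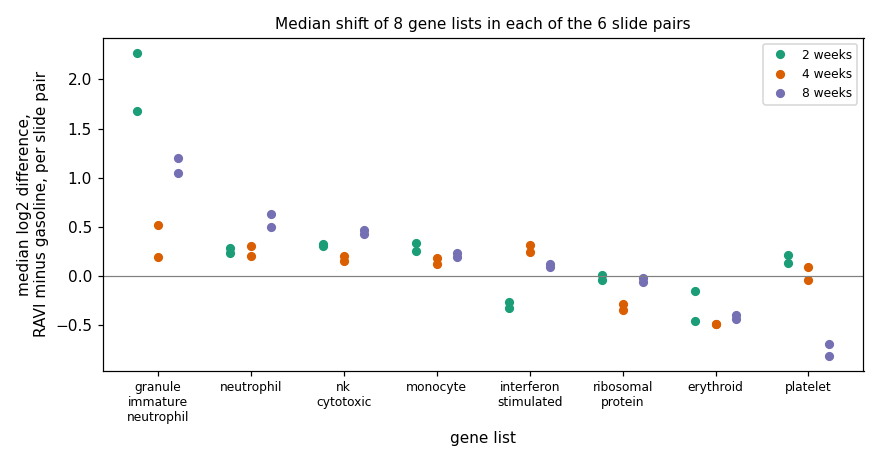
Median log2 difference (RAVI minus gasoline heater, vertical axis) of 8 gene lists (horizontal axis) in each of the 6 slide pairs; each point is 1 pair, coloured by week. The granule-protein median lies above 0 in each pair, from 0.19 to 2.27, and the interferon median lies below 0 in both 2-week pairs, at -0.27 and -0.32.

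The comparisons of times ask how blood expression moved over the sampled weeks, with no array labelled as taken before vaccination. They average the rooms, also for genes whose rooms moved differently. From 2 to 4 weeks the antiviral genes induced by interferon fell. CXCL10 (494019), a chemokine, fell by 4.04 (SE 0.098, 16.4-fold lower, adjusted p = 1.44e-06), RSAD2 fell by 2.07 (SE 0.069), BST2 fell by 1.91 (SE 0.080) and MX2 fell by 1.79 (SE 0.067). Of 22 list genes 21 were lower and 0 higher (21 adjusted over the list alone), with a median of -1.28 (camera adjusted p = 4.87e-08, adjusted p = 0.375 with an estimated correlation). Granule-protein genes fell too, PR39 by a log2 change of -2.28 (SE 0.073), LTF -2.12 (SE 0.081), PMAP-23 -2.06 (SE 0.113) and NPG4 -1.90 (SE 0.082), with 7 of 8 lower and 1 higher (7 and 1 adjusted over the list alone, median -1.58, camera adjusted p = 0.0137, adjusted p = 0.779 with an estimated correlation). The rooms differed in this: PR39 had -0.90 with the gasoline heater and -3.65 with RAVI, and NPG4 -0.43 and -3.36, both with an interaction past the threshold. Heat shock genes fell, with 10 of 11 lower (11 adjusted over the list alone, median -0.67, camera adjusted p = 0.0111, adjusted p = 0.779 with an estimated correlation), among them HSP70.2 (-1.05), HSPA6 (-0.95), HSP90AA1 (-0.81) and HSPD1 (-0.72). Erythroid genes rose, 5 of 6 (also 5 adjusted over the list alone, median +0.48, camera adjusted p = 0.00285, adjusted p = 0.301 with an estimated correlation), with RHCE at +0.69, TFRC at +0.57 (below background in both groups, and adjusted p = 0.0973 with slide as a block) and FAM210B at +0.25 (2 of 3 probes). In the ribosomal list 15 of 34 were higher (13 adjusted over the list alone), RPS10 (+0.55), RPL32 (+0.46, and -0.02 under normexp), RPL11 (+0.44) and RPS16 (+0.43) first, with a median of +0.22 that was -0.08 under quantile scaling and -0.10 under normexp, where the call of adjusted p = 2.7e-07 was lost. The ribosomal list stood at adjusted p = 0.779 with an estimated correlation.

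Further genes lower at 4 than at 2 weeks were the antibody receptor FCGR1A (-4.48, at least 5.55-fold lower), OASL (-2.93), the receptor kinase AXL (-2.77, at least 3.20-fold lower), TNNC1 (-2.72, above background only on the RAVI arrays at 2 weeks), USP18, an interferon-induced protease (-2.22), EDN1 (-2.20, at least 1.12-fold lower) and CYP3A46 (-2.11, above background on 3 of 4 arrays at 2 weeks and 0 at 4 weeks). The largest rises were PAGE2B (+1.68, SE 0.108), UNC45B (+1.24), LUM (+1.23), ACAN (+1.20), TEAD1 (+1.19), HSD17B8 (+1.16, 1 of 3 probes), CMYA5 (+1.11), CAV3 and KLF14 (each 2.15-fold), and XPNPEP2 (+1.07). In all 8737 features differed, 4879 higher and 3858 lower, while among the 1199 named ones 869 were lower. The higher share of 55.8% was 66.1% where the percentile was taken over probes above background on all arrays (6188 and 3177) and 38.6% under median scaling (2819 and 4483). The median over all features shifted by +0.14 from 2 to 4 weeks, +0.16 from 4 to 8 weeks and +0.12 from 2 to 8 weeks, with -0.17, +0.01 and -0.24 for named features, so that changes over time are best read against these shifts.

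From 4 to 8 weeks myeloid genes fell and lymphocyte genes rose. ARG1 (397115) fell by 2.79 (SE 0.067, 6.92-fold lower), S100A9 (100127489) fell by 1.87 (SE 0.072), TREM1 fell by 1.57 (SE 0.084) and S100A12 fell by 1.47 (SE 0.077), with 9 of 11 neutrophil genes lower and 1 higher (9 and 1 adjusted over the list alone, median -1.35, camera adjusted p = 0.00145, adjusted p = 0.529 with an estimated correlation). Of 22 monocyte genes 17 were lower and 1 higher (18 and 1 adjusted over the list alone, median -0.76, camera adjusted p = 0.000368, adjusted p = 0.605 with an estimated correlation), with VSIG4 at -1.93, CD14 at -1.84, TLR4 at -1.67 and HMOX1 at -1.41 (SE 0.085). Platelet genes were lower in 11 of 14 (also 11 adjusted over the list alone, median -0.65, camera adjusted p = 0.00316, adjusted p = 0.529 with an estimated correlation), with PPBP at -1.32, CLU at -1.13, ITGA2B at -0.90 and TUBB1 at -0.72. T cell genes were higher in 10 of 14 (also 10 adjusted over the list alone, median +0.39, camera adjusted p = 0.00154, adjusted p = 0.529 with an estimated correlation), with CD3D at +1.08 (1 of 2 probes), LEF1 at +0.82, GATA3 at +0.71 and CD69 at +0.54. B cell genes were higher in 5 of 7 (also 5 adjusted over the list alone, median +0.36, camera adjusted p = 0.0389, adjusted p = 0.664 with an estimated correlation), led by the surrogate light chain VPREB1 (+1.49, SE 0.082), then CD79A (+0.48), CD72 (+0.39) and MS4A1 (+0.36).

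The antioxidant, glucocorticoid and inflammasome lists also fell from 4 to 8 weeks. Other stress lists were not called: heat shock (camera adjusted p = 0.661), hypoxia (0.836) and the unfolded protein response (0.904). The erythroid list, which had risen from 2 to 4 weeks, was not called either (camera adjusted p = 0.0934, 0.529 with an estimated correlation). Its median was nonetheless -1.23, with 4 of 6 genes lower and 1 higher, and fry gave it adjusted p = 1.24e-07. Whether the antioxidant falls are separate from this erythroid fall was not tested. In the antioxidant list 12 of 20 were lower and 3 higher (12 and 3 adjusted over the list alone, median -0.52, camera adjusted p = 0.0389, adjusted p = 0.765 with an estimated correlation), with PRDX2 (-1.74), HMOX1, FTH1 (-1.25) and CAT (-1.17). In the glucocorticoid list 8 of 11 were lower and 1 higher (8 and 1 adjusted over the list alone, median -0.55, camera adjusted p = 0.0367, adjusted p = 0.664 with an estimated correlation), with CD163 (-1.37), CEBPB (-1.23, above background on 2 of 4 arrays at 4 weeks and 0 at 8 weeks), ALOX5AP (-1.17) and SGK1 (-1.02). In the inflammasome list 4 of 5 were lower (also 4 adjusted over the list alone, median -0.55, camera adjusted p = 0.0367, adjusted p = 0.529 with an estimated correlation), IL18 (-1.83, SE 0.069), IL1B (-0.88), CASP1 (-0.55) and TXNIP (-0.47). Interferon-induced genes were lower in 12 of 22 and higher in 3 (12 and 3 adjusted over the list alone, median -0.48), with IRF7 (100037289) at -2.18 (SE 0.081), IFIT1 at -1.98, MX1 at -1.02 and STAT2 at -0.85, but that call (adjusted p = 0.0389) was lost with slide as a block (0.0642), and it stood at 0.664 with an estimated correlation.

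The largest single falls from 4 to 8 weeks included ISG12(A) (-4.17, SE 0.110), FAAH (-4.04), the xenobiotic receptor NR1I2 (-4.01), APOA5 (-3.59), the peptide transporter TAP2 (-3.38), CLPS (-3.29), PTGDS (-3.26), ACR (-3.07) and RHBG (-3.04). ISG12(A) is known as an interferon-induced gene but did not follow the interferon list. From 2 to 4 weeks it had +0.101 with the gasoline heater and +0.585 with RAVI, when 21 of 22 list genes fell. The fall of TAP2 was not shared by the MHC class I list that holds it, with a median of -0.007 (3 of 14 genes higher and 4 lower, camera adjusted p = 0.982). Each gene named among these falls also shared deviations of single arrays. In RAVI, replicate 2 lay below replicate 1 at 2 weeks and above it at 4 weeks, for APOA5 with 6.04 against 6.54 and 7.39 against 6.93. Whether their probes share a source of signal was not tested, so these may not be separate changes. The rises were LY49, a killer cell lectin receptor (+2.30, at least 2.81-fold), SSTR5 (+1.82, at least 1.19-fold), RHOV (+1.80, at least 1.28-fold), BEX1 (+1.76, below background at 4 weeks), the clock gene ARNTL (+1.69), VPREB1, GUCA2B (+1.26), the granzyme GZMH (+1.25), LOC396700 (+1.20) and ACVR2A (+1.18, at least 1.51-fold). In all 10507 features differed, 6516 higher and 3991 lower, and 658 of the 1241 named ones were lower.

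Over the whole interval from 2 to 8 weeks each of the 22 measured interferon-induced genes fell (22 adjusted over the list alone). CXCL10 fell by 4.59 (SE 0.098, 24.0-fold lower), MX1 fell by 2.82 (SE 0.089), IRF7 fell by 2.40 (SE 0.081) and RSAD2 fell by 2.12 (SE 0.069), with a list median of -1.74 (camera adjusted p = 5.49e-08, adjusted p = 0.63 with an estimated correlation). Each of the 8 lists called from 2 to 8 weeks stood at that adjusted p = 0.63. Monocyte genes were lower in 21 of 22 (also 21 adjusted over the list alone, median -1.15, camera adjusted p = 3.37e-05), with FCGR1A (-3.98, at least 8.83-fold lower), HMOX1 (-2.20, SE 0.085), TLR4 (-2.06) and FCN1 (-1.70). Neutrophil genes were lower in 10 of 11 (also 10 adjusted over the list alone, median -1.52, camera adjusted p = 0.00183), with S100A9 (-2.81, SE 0.072), S100A12 (-2.45), S100A8 (-2.33) and ARG1 (-2.19). The antioxidant list was lower in 15 of 20 and higher in 1 (15 and 1 adjusted over the list alone, median -0.72, camera adjusted p = 0.026), with CAT (-1.44), TKT (-1.29) and PRDX6 (-0.93) beside HMOX1. Granule-protein genes were lower in 7 of 8 and higher in 1 (7 and 1 adjusted over the list alone, median -1.70), with LTF (-3.03, SE 0.081), NPG4 (-2.14), LCN2 (-1.80) and PR39 (-1.59), and platelet genes in 10 of 14 (also 10 adjusted over the list alone, median -1.41), with CLU (-2.59, SE 0.067), TUBB1 (-1.82), SELP (-1.55) and ITGA2B (-1.53). The granule-protein call (adjusted p = 0.026) and the platelet call (0.0276) were lost with slide as a block, at adjusted p = 0.0581 and 0.06.

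T cell genes were higher at 8 than at 2 weeks in 6 of 14 and lower in 3 (6 and 3 adjusted over the list alone, median +0.11, camera adjusted p = 0.0218), with CD3D at +1.30 (1 of 2 probes), LEF1 at +0.72 (2 of 3 probes), CD69 at +0.43 and IL7R at +0.36 (1 of 2 probes). Ribosomal genes were higher in 16 of 34 and lower in 1 (15 and 1 adjusted over the list alone, median +0.25, camera adjusted p = 5.24e-06), with RPS10 and RPS16 at +0.72, RPL23 at +0.49 and RPL11 at +0.47. Other named falls were ISG12(A) (-3.83), FAAH (-3.53), the chemokine CCL8 (-3.39, at least 7.94-fold lower), TNNC1 (-3.24, above background only on the RAVI arrays at 2 weeks), NR1I2 (-3.24), the complement inhibitor SERPING1 (-3.02, SE 0.072) and EDN1 (-2.99, at least 1.78-fold lower). ISG12(A), FAAH and NR1I2 are among the genes given above that shared deviations of single arrays. Rises were LY49 (+2.53, SE 0.190), SSTR5 (+2.16, at least 1.49-fold), RHOV (+1.88, at least 1.60-fold), GABBR1 (+1.72), SNCAIP (+1.65), GUCA2B (+1.63), SLC25A27 (+1.57), APOA1 (+1.56), UROC1 (+1.55, 1 of 2 probes) and ARNTL (+1.52, 1 of 3 probes). In all 11090 features differed, 6582 higher and 4508 lower, and 981 of the 1362 named ones were lower. The higher share of 59.4% was 69.7% where the percentile was taken over probes above background on all arrays (7947 and 3461) and 53.3% under median scaling (5635 and 4945).

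**Figure D4:**
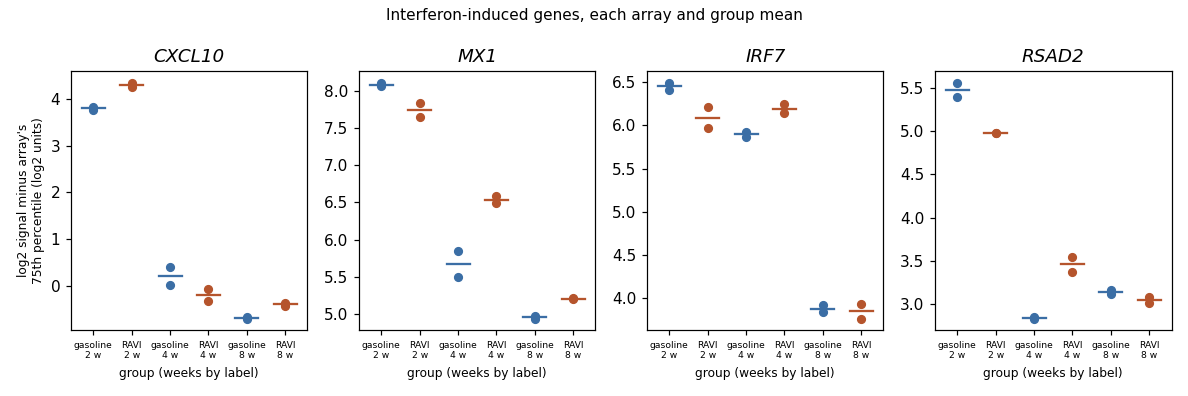
Signals of 4 interferon-induced genes (log2 units relative to each array's 75th percentile, vertical axis) in the 6 groups (horizontal axis); points are arrays and lines are means of 2 arrays. CXCL10 falls from 3.80 at 2 weeks to -0.68 at 8 weeks with the gasoline heater and from 4.30 to -0.40 with RAVI.

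Within each heater, the F tests over the 3 times called 10630 features for the gasoline heater, 1321 of them named, and 11123 for RAVI, 1483 of them named. In the gasoline heater room FABP6 (adjusted p = 3.79e-08) was below background at 2 weeks and had a mean signal of 3.70 at 8 weeks. From 2 to 8 weeks ARG1 (2.75e-06) had -2.85 there, CXCL10 (3.41e-06) -4.48, S100A9 (3.41e-06) -3.07 and ISG12(A) (3.41e-06) -3.97. In the RAVI room CXCL10 (3.16e-06) had -4.69 over that interval, CLU (3.16e-06) -3.56, SERPING1 (3.91e-06) -3.22, NPG4 (3.91e-06) -3.01 and PR39 (3.16e-06) -2.70. PR39 had -0.49 and NPG4 -1.27 in the gasoline heater room over that interval.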

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

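Of the tests in this part, the comparison with the neutrophil list, the look at array positions and the scaling test of the interferon list were chosen after the result was seen. The SEs in this part are taken over the genes of a list, which share the same arrays and are not independent. They hold no spread between arrays or pigs. What marks the results below is that the heater effect differed among the 3 times, by an interaction test at adjusted p under 0.05 for genes and by camera on the difference of 2 heater effects for lists. It did for 310 features.

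Among named genes, FABP6 turned from higher with RAVI at 2 weeks (+4.55) to lower at 8 weeks (-5.08; interaction adjusted p = 1.4e-07), and past the threshold at both times so did MUL1 (+0.95 and -3.18; 6.03e-05), VWF (+0.92 and -1.46; 0.00446) and CLU (+0.73 and -1.21; 0.000403). C1QB (0.00179) was higher at 2 weeks (+1.23), and at 8 weeks both groups were below background. By the interaction alone, as the 2-week difference did not pass, the effect moved for ITGA2B (+0.34 and -0.92; 0.00483), TUBB1 (+0.14 and -0.82; 0.0295), MYL9 (+0.30 and -1.31; 0.0264) and CNN1 (+0.47 and -1.64; 0.00527). The granule-protein genes PR39 (0.000125), NPG4 (0.000212), PMAP-23 (0.0012) and LCN2 (0.00981) had their smallest difference at 4 weeks, when LCN2 was negative (-0.32) and did not pass. TNNC1 (0.000496), TNNT1 (0.0214), MYL2 (0.0252) and CCNB1 (0.0325) were higher with RAVI at 2 weeks and did not pass at 4 weeks. RSAD2 (0.0157), MX2 (0.0214), OAS2 (0.0297), MX1 (0.0325) and EIF2AK2 (0.0363) were higher with RAVI at 4 weeks, whereas their 2-week differences were negative and did not pass, and ZBP1 (0.0325) went from -0.53 at 2 weeks to +0.40 at 8 weeks. Differences were largest at 8 weeks for KLRK1 (+1.71; 0.0157), GZMA (+1.66; 0.0263), IL18 (+1.41; 0.0109), SDHD (+0.97; 0.0402), IL10 (+0.95; 0.0325) and LOC100302368 (-1.93; 0.00657). RAG2 (-4.34; 0.00569), SRPK3 (-2.42; 0.0342) and CD1E (-2.10; 0.0107) were above background only in the gasoline heater group at 8 weeks. ARG1 went from -0.76 at 2 weeks to +0.56 at 8 weeks (0.00477). CCR1 (+0.64; 0.0432) and SERPINF1 (-0.68; 0.0237) differed most at 4 weeks, when CEBPB (+1.53; 0.0275) was below background with the gasoline heater.

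From 2 to 4 weeks the RAVI minus gasoline difference moved for the lists of interferon (median +0.64, adjusted p = 1.78e-12, 0.15 with an estimated correlation), granule-protein (-2.04, 4.9e-08, 0.15), respiratory chain (-0.47, 1.04e-05, 0.819), ribosomal (-0.32, 0.00172, 0.994), cell division (-0.53, 0.00843, 0.819) and MHC class II genes (-0.37, 0.0208, 0.917). From 2 to 8 weeks it moved for interferon (+0.37, 1.59e-07, 0.398), platelet (-1.11, 2.2e-05, 0.398), granule-protein (-0.93, 4.1e-05, 0.398), cell division (-0.44, 0.00644, 0.441), inflammasome (+0.44, 0.0259, 0.401) and cytotoxic genes (+0.10, 0.0259, 0.922). From 4 to 8 weeks it moved for platelet (-0.82, 8.89e-06, 0.718), respiratory chain (+0.47, 4.8e-05, 0.785), MHC class II (+0.47, 0.000353, 0.785), ribosomal (+0.29, 0.000693, 0.805), granule-protein (+0.92, 0.00128, 0.718), complement (-0.20, 0.033, 0.785), interferon (-0.25, 0.043, 0.805) and B cell genes (+0.36, 0.0472, 0.805). Those for inflammasome, cytotoxic and B cell genes were lost with slide as a block, at adjusted p = 0.0888, 0.0521 and 0.0867.

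The granule-protein list was higher with RAVI by a median of 1.24 over the times. A signal gradient along the slide is argued against, since the later array positions moved the list by a median of 0.021 (SE over its genes 0.027, highest gene 0.165). More neutrophils of every stage are argued against as the whole cause on these arrays. The fixed neutrophil list, which is not limited to the mature stage, rose by 0.26. The granule-protein list exceeded it by 0.981 (bootstrap SE over genes 0.414). At 4 weeks on slide 2 the granule-protein median was 0.192 and the neutrophil median 0.304, while in the other slide pairs the granule-protein median was the higher. What stays open is the room or the array position, as 0 RAVI arrays stood at odd positions and each heater had its own room, so these cannot be told apart from the heater. A larger share of immature neutrophils in the RAVI pigs may also contribute and was not tested apart from these genes.

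Some muscle transcripts were high in RAVI at 2 weeks and RAG1, RAG2 and CD1E in the gasoline heater group at 8 weeks, which could be RNA from other cells in those samples. RAG1 was not limited to that group and was above background on 4 of 12 arrays. It had -0.788 on replicate 1 and -3.809 on replicate 2 of RAVI at 4 weeks, against -0.444 and -0.42 in the gasoline heater group at 8 weeks. For skeletal muscle, the 18 other muscle genes had a median difference of 0.246 (SE 0.231; 14 higher). That met the bound against muscle written before the test, under 0.5 by more than 1 SE. The bound was set aside only after the result was seen. The reason was that 9 of the 18 were above background on each array, with ACTA1 at 5.05 in the gasoline heater group already, where a small share would not show. Genes near the floor were mixed. MYH7 rose from -3.88 to -0.01 and TNNC2 from -3.67 to -2.33. MYH1 (-3.53 to -4.36), MYH2 (-5.00 to -5.16) and CASQ1 (-2.98 to -3.19) did not rise. As written the test counts against skeletal muscle in general, and RNA of some muscle genes stays open. For thymocytes, the 5 other marker genes were higher in the gasoline heater group by a median of 0.312 (SE 0.19; 3 higher), between the bounds set for and against, which leaves that open too. The labels name no biological difference limited to these groups beyond heater and time.

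The interferon-induced genes fell from 2 to 8 weeks, with a median change of -1.74. Array scaling is argued against, since the list's median relative to all named genes, -1.51 as reported, was -1.423 under quantile scaling and -1.408 under normexp. The other scalings shift whole arrays and cannot move that value. A slide batch is argued against, since on the slide that holds both times the median was -1.697 (SE 0.198; 22 of 22 lower). A compression that depends on signal is argued against, since 0% of 10000 random lists matched on signal had a median as low (lowest -0.90). A fading response to an earlier stimulus, or the age of the pigs, may underlie it as an untested hypothesis. Vaccination could be that stimulus only if the weeks count from it, and no array is labelled as taken before it. That count conflicts with the labelled housing of 8 weeks, because vaccination came 2 weeks after entry. On the rearing count the 2-week arrays fall at vaccination, so their high interferon signal would not be a fading response to it.

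Splits of the arrays within each time were drawn to ask what chance regrouping gives. They cannot speak to chance differences between pigs or rooms, since each heater had 1 room and an array may hold 1 pig or a pool. For the averaged heater effect, 1 of 100 splits, the real one, called as many features as the real 1221, and the highest other called 988, so a chance regrouping of these arrays is argued against at that level. That other split follows the slides at 2 and 4 weeks and the heater at 8 weeks, and the splits that keep each slide pair together called 625, 473, 19 and 0. The real count was 2816 with slide as a block. Among the 28 drawn splits that part all 6 slide pairs, as the real one does, the highest other called 320. For lists, 4 of 100 splits called at least the real 10 (highest other 12), which is below the share set before the test. Of the 28 that part all pairs, 4 did so too. Only these share the slide layout of the real split, so chance is not excluded for the number of lists. Between times, in an additive model, the real split alone of 35 called as many features for 4 minus 2 weeks (1 of 35; 8401, highest other 222), 8 minus 4 weeks (1 of 35; 10186, highest other 1) and 8 minus 2 weeks (1 of 35; 10803, highest other 2), which argues against a chance regrouping of these arrays. For the numbers of lists between times a chance regrouping is not excluded: 8 of 35 splits called as many for 4 minus 2 weeks (real 5, highest other 7), 23 of 35 for 8 minus 4 weeks (real 3, highest other 10) and 9 of 35 for 8 minus 2 weeks (real 6, highest other 9).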

How the results depend on the processing

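Normexp on median signals, the percentile over probes above background on all arrays, the all-features background for lists and the leaving out of whole times were chosen after seeing the data. Apart from single arrays left out, 180 counts stayed within 1.5 times the reported value, 28 fell below and 24 rose above. Of gene values 4307 kept direction and side of the threshold, 263 lost and 199 gained a call, 11 reversed and 47 without a test moved; of list values 744 kept both, 122 lost a call (59 of them with an estimated correlation) and 2 reversed in the direction of the list test. F tests of named genes kept their side in 177 of 177. The cause of a change was not tested except where given.

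Under median scaling the heater effect called 628 features averaged over times and 83, 80 and 512 at 2, 4 and 8 weeks, with 151 for the interaction. Without a filter on dim probes these were 236, 28, 16, 199 and 79, with 5620 for 4 minus 2 weeks, where more features share the correction; lists called were 8 at 8 weeks and 11 for 4 minus 2 weeks. With the filter asking for signal on all arrays 5 lists were called for the averaged effect, and with the mean over probes 8 lists for 4 minus 2 weeks.

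With slide as a fixed block the 5 feature counts were 2816, 684, 539, 1677 and 566, and as a random block 2958, 1054, 948, 2247 and 1262. With the 6 slide pairs as the block they were 2099 averaged, 95 at 4 weeks and 171 for the interaction. That pair block ended the list calls for glucocorticoid, monocyte and neutrophil genes averaged over times and for B cell and erythroid genes at 4 weeks. The additive model gave 579 for the averaged effect, leaving out the 2-week arrays 468 and leaving out the 8-week arrays 116, where fewer arrays were used. Fits to only the groups compared, with fewer degrees of freedom, gave 13 at 2 weeks, 0 at 4 weeks (limma; 1003 at unadjusted p under 0.05) and 341 at 8 weeks.

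Camera with an estimated correlation called 0 lists in each of the 7 comparisons, with 2, 4, 1, 3, 2, 0 and 1 at unadjusted p under 0.05, as it allows for correlation within lists. Fry called 17 averaged, 8 at 2 weeks, 9 at 4 weeks, 9 at 8 weeks, and 27, 21 and 29 for 4 minus 2, 8 minus 4 and 8 minus 2 weeks. Against all features camera called 17 averaged, 14 at 2 weeks, 16 at 8 weeks, 25 for 4 minus 2 weeks and 23 for 8 minus 2 weeks.

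Reversed under normexp were RPL32 (-0.016) and the ribosomal list (-0.096) for 4 minus 2 weeks. The ribosomal list median, though not its test direction, also changed sign for 4 minus 2 weeks under quantile scaling (-0.075) and for the averaged effect under quantile scaling (0.009) and normexp (0.019). Reversed under median scaling were IL1B averaged (0.032) and at 2 weeks (0.003). ARNTL for 8 minus 2 weeks was -0.264 with the filter on all arrays, and UROC1 -0.014 with the mean over probes, where other probes of the gene are used. Without the 8-week arrays the averaged effects of ITGA2B (0.135), TUBB1 (0.081), MYL9 (0.227), CD4 (0.117) and the platelet list (0.131) reversed. Within single slide pairs the averaged effect was reversed for PMAP-36 at 4 weeks on slide 2 (-0.239) and LOC100626841 at 2 weeks on slide 3 (0.038, below background).

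Leaving out each array in turn assumes that the lone array left varies like the other groups. It gave 511 to 1255 features for the averaged effect, 30 to 276 at 2 weeks, 49 to 231 at 4 weeks, 218 to 996 at 8 weeks and 111 to 355 for the interaction. In the order gasoline heater replicates 1 and 2, then RAVI replicates 1 and 2, leaving out a 2-week array gave 804, 752, 640 and 726 averaged, 63, 57, 30 and 73 at 2 weeks, 141, 141, 107 and 107 at 4 weeks and 180, 192, 162 and 192 for the interaction. Leaving out an 8-week array gave 511, 575, 623 and 576 averaged, 111, 111, 114 and 114 at 2 weeks, 91, 91, 92 and 92 at 4 weeks, 238, 225, 345 and 218 at 8 weeks and 122, 111, 135 and 121 for the interaction. Among 4-week arrays, only the RAVI ones moved a count by over 1.5 times, that at 4 weeks, to 49 and 125. For times it gave 7086 to 9039, 9062 to 10430 and 9977 to 11344, and for the F tests 8028 to 10906 and 8972 to 11588. Lists called ranged from 7 to 11 averaged, 5 to 7, 10 to 15 and 4 to 6 by time, and 5 to 7, 7 to 11 and 8 to 9 between times. Genes that reversed had no call: IL1B averaged (-0.058 to 0.047) and at 2 weeks (-0.015 to 0.015), and at 4 weeks TNF (-0.065 to 0.189), CD4 (-0.308 to 0.161) and IL10 (-0.217 to 0.025). Depth limits dim genes: 42.2% to 53.3% of probes were well above background.

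Normexp on mean signals was replaced as stated in the methods, and lists were not run with slide as a random block.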

Other observations

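In the 7 comparisons 10 of the 31 tested lists were called in none. The smallest camera adjusted p was 0.0584 for glycolysis (8 minus 2 weeks, median -0.73, 9 of 10 genes lower), 0.102 for immediate early genes (heater at 4 weeks, +0.15), 0.112 for MHC class I (8 minus 2 weeks, -0.37), 0.124 for eosinophil, basophil and mast cell genes (8 minus 4 weeks, -0.67), 0.156 for apoptosis (heater at 4 weeks, +0.03), 0.2 for the unfolded protein response (8 minus 2 weeks, -0.38), 0.238 for hypoxia (4 minus 2 weeks, -0.42), 0.399 for p53 targets (heater at 8 weeks, 0.002), 0.52 for lipid metabolism (4 minus 2 weeks, -0.44) and 0.716 for pattern recognition receptors (heater at 4 weeks, -0.02).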
